A study of Mus musculus with 36 samples.

How the data were processed

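Messenger RNA was measured in lung tissue of female C57BL/6 mice, a common inbred laboratory strain, after 1 intranasal instillation of graphene oxide sheets or of the 5% dextrose carrier. Per the labels' protocols, small pieces of each lobe were taken once the large airways had been dissected away, RNA with an integrity number under 8 was discarded, and stranded libraries were made from polyadenylated RNA. The labels give 12 groups of 3 libraries each, 36 in all, from 4 materials (D, US, S and L) at days 1, 7 and 28. A group held 4 to 5 animals per the labels' protocols, and no label ties a library to an animal, so p-values measure the spread between these samples. Material marked MWCNT and a day 90, which the protocols mention, were not analysed here.

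The deposited count table holds whole read counts per Ensembl gene for 46078 genes, as its values show, and the submitters' processing notes list bcl2fastq 2.19.1.403, CASAVA, STAR 2.5.1b (a read aligner), featureCounts 1.5.1 (a read counter) and StringTie 1.3.3 (a transcript quantifier) without their roles. Those notes name the builds GRCh37 and GRCm38, and the scaffold names in the deposited StringTie tables are those of GRCm38, the mouse build used for the positions given here. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical gene copies, cannot be apportioned with certainty. The authors also deposited TPM values (transcript abundance scaled to the same total in each library), which served as an alternative measure. FPKM values and coverage, a mean read signal per base of each gene, stand in the same deposited tables per the file headers and were not used here.

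Total counts ran from 16154696 to 23808264 in 35 libraries and reached 80566751 in S day 7 replicate 2, 4.13 times the median of the others. CPM, the count scaled to the library total, was used for levels. A gene at 1 CPM therefore rested on 16.2 to 23.8 counts in those 35 libraries. Libraries of a group were compared before averaging: the chi-square per degree of freedom between their counts was at least 6.534, far above sampling noise, so none was counted as a duplicate. The lowest correlation of log CPM within a group was 0.9716.

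The following choices were made before the data were examined: the test, the libraries in the fit, the 35 gene lists, the rule for named genes and most alternatives. Genes were filtered with edgeR's filterByExpr over the 12 groups, which left 16903. Counts were scaled by TMM (factors 0.9322 to 1.059) and fitted in edgeR 4.0.16 under R 4.3.3, with a mean per group and all 36 libraries in 1 fit, since 3 libraries per group alone leave few degrees of freedom. Each comparison was tested with the two-sided quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Each size was compared with D of the same day, each pair of sizes was compared within a day, the effect of each size was compared between days 28 and 1 as an interaction, and D groups were compared over time. Fold changes are fitted log2 values ± standard error (SE), and CPM values are means ± SD of 3 libraries.

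The lists covered inflammatory cells and mediators, lung cell types, other tissues that a lung sample could hold, and stress and timing programmes. A list needed 5 measured members, which left 33. Lists were tested with camera of limma 3.58.1 on voom values, at a preset correlation of 0.01 between genes, and adjusted over lists and comparisons, separately for comparisons with D and between sizes. The median given for a list is that of its members' voom log2 fold changes unless another is named. With an estimated correlation 1 of the 89 list calls against D held and 0 of the 70 between sizes, and fry, which tests whether members of a list move on balance in 1 direction without a comparison to other genes, called 10 and 4.

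For comparisons with D, named genes were the 10 largest and 10 smallest fold changes among genes that passed the threshold, averaged at least 1 CPM and had the 3 exposed libraries on the same side of the 3 D libraries, plus up to 3 called members of each list with the smallest p. For the other comparisons the 5 largest and 5 smallest were taken, without the condition on sides for interactions. Fewer were named where that sufficed, and any other gene is marked as chosen after its values were seen.

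Alternatives were DESeq2's size factors in edgeR (RLE), no filter on low counts, a replicate block, DESeq2 1.42.0, a fit of only the groups compared, limma on log2(TPM + 1) for genes with a mean of at least 1 TPM, and leaving out each library in turn. Offsets for GC content and transcript length (Biostrings 2.70.1, available for 99.6% of the tested genes), a fat score and a clock score as covariates, and a thinned S day 7 replicate 2 were added after seeing the data. For the similarity of effects, a mean of at least 10 CPM was also tried. No scaling moved the median log2 fold change of all genes by more than 0.031.

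The fits were tested on simulated data without the structure of the real samples, so real recovery may be lower. With 200 changed genes drawn on the real means, edgeR recovered 87% of 2-fold and 98% of 4-fold changes for US against D at day 7 (16701 genes). The shares were 86% and 99% for L against D at day 28 (16686 genes), and 70% and 89% for the L interaction (16712). In a simulated GC trend over 16903 genes the offsets took false calls from 2221 to 0.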

Results

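Lung RNA was profiled in mice given sheets of graphene oxide, an oxidised form of the carbon sheet graphene, as 1 intranasal dose of 50 μg, to ask whether the lateral size of the sheets matters for the early and the late response of the lung. The materials are marked US, S and L in the labels (ultrasmall, small and large sheets in the study's naming), and D marks mice that received the 5% dextrose carrier alone (0 μg). Lungs were taken at days 1, 7 and 28, when the mice were 9, 10 and 13 weeks old. There were 3 libraries in each of the 12 groups (n = 3 throughout). Total counts per library were 16154696 to 23808264, apart from S day 7 replicate 2 at 80566751, and 16903 genes were tested. The first principal component held 30.8% of the variance of log CPM and the second 9.57%.

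The genes at the centre of the comparisons lie as follows in GRCm38, each span being the whole annotated gene with its exons and introns. Cxcl5 (ENSMUSG00000029371), a chemokine that attracts neutrophils, spans 90759360 to 90761624 on chromosome 5. Mmp12 (ENSMUSG00000049723), the elastase of macrophages, spans 7344381 to 7369499 on chromosome 9, and Gpnmb (ENSMUSG00000029816), a glycoprotein of lysosome-rich macrophages, 49036518 to 49058182 on chromosome 6. Trem2 (ENSMUSG00000023992), a lipid-sensing receptor of macrophages, spans 48346401 to 48354147 on chromosome 17. Of the clock genes, Npas2 (ENSMUSG00000026077) spans 39193731 to 39363236 on chromosome 1, Dbp (ENSMUSG00000059824) 45705088 to 45710155 on chromosome 7, and Nr1d1 (ENSMUSG00000020889) 98767932 to 98775333 on chromosome 11.

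**Figure D1:**
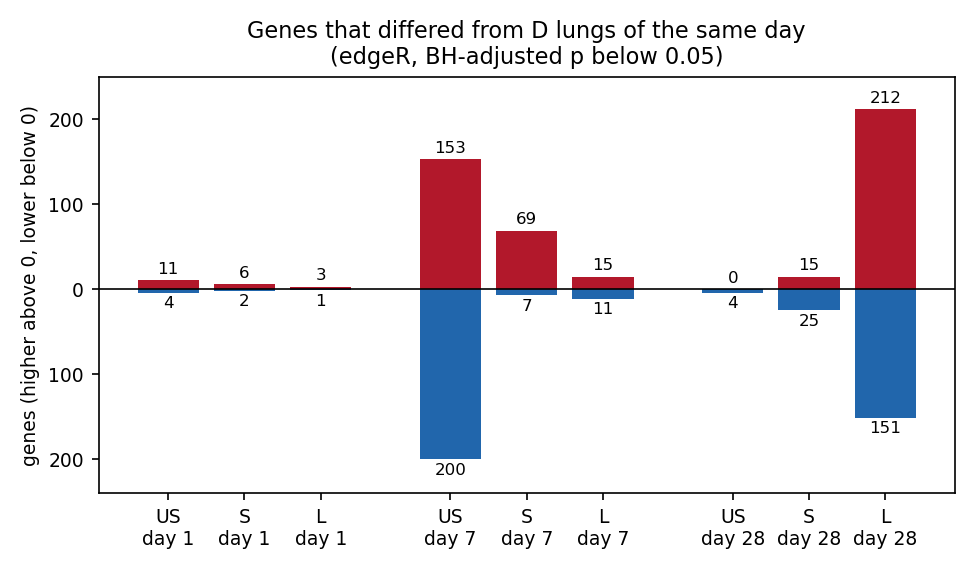
Number of genes that differed from D lungs of the same day for each size and day (bars above 0 are genes higher in exposed lungs, bars below 0 genes lower, edgeR, adjusted p below 0.05). The tallest bars are US at day 7 (153 higher, 200 lower) and L at day 28 (212 higher, 151 lower).

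At day 1, US lungs carried more transcript of neutrophil-attracting genes than D lungs, and of neutrophil markers, the latter most of all in replicate 1. Cxcl5 was 26.0-fold higher (log2 fold change 4.70 ± 0.80, 14.6 ± 5.56 against 0.558 ± 0.317 CPM, adjusted p = 0.0113). Cxcl1, a chemokine of the same class, was 9.23-fold higher (3.21 ± 0.60), and Il1r2, the decoy receptor for interleukin 1, was 20.4-fold higher (4.35 ± 0.85). Lcn2 (ENSMUSG00000026822), which encodes the iron-sequestering acute-phase protein lipocalin 2, was 7.72-fold higher (2.95 ± 0.55), at 1400 ± 1130 against 182 ± 59.1 CPM. Hcar2, Steap4 and Vnn3 rose 3.05-, 2.74- and 2.54-fold, and Slco5a1 (3.17-fold), Ccdc28a (1.79-fold) and Lifr (1.37-fold) fell. Of 12 measured neutrophil-attracting chemokines and acute cytokines, 2 rose, 0 fell and 10 were not called, while 10 rose adjusted over the list alone (median log2 1.43, camera adjusted p = 3.1e-08, adjusted p = 0.275 with an estimated correlation). Of 13 neutrophil markers 1 rose and 12 were not called, with 9 higher adjusted over the list alone (median 1.04, adjusted p = 3.41e-06, adjusted p = 0.473 with an estimated correlation). Of 14 acute-phase and mucosal defence genes 1 rose and 13 were not called, with 13 higher adjusted over the list alone (median 1.47, adjusted p = 1.03e-08, adjusted p = 0.386 with an estimated correlation). T and NK cell markers shifted down as a list of 21 (median -0.68, adjusted p = 4.3e-07, adjusted p = 0.728 with an estimated correlation), with 0 members called. The neutrophil score of replicate 1 (mean log2 CPM of the markers relative to all libraries) was 1.97, against 0.14 and 0.42 in the other US libraries, and its T and NK cell score -1.57, against -0.12 and -0.37 (0.03, 0.05 and -0.08 in D).

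The edgeR test called 15 genes in US against D at day 1 (11 higher, 4 lower), beside 2724 at an unadjusted p under 0.05. Leaving out D replicate 1, 2 or 3 gave 0, 2 or 7 genes, and leaving out US replicate 1, 2 or 3 gave 3, 887 or 1.2e2. Of 12 named genes, 12, 11 or 9 lost their calls without D replicate 1, 2 or 3 (Cxcl5 each time, adjusted p up to 0.2) and 11 without US replicate 1 (Il1r2 among them, adjusted p = 0.602). DESeq2 called 347, the fit without a filter on low counts 137, the fit with GC and length trends removed 448, that with a clock score 141, that of only the groups compared 2, and limma on TPM 1.

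At day 1, S lungs differed from D lungs in 8 genes at the edgeR threshold, 4 of them members of the fixed list of 15 clock genes. Hlf and Tef, output factors of the circadian clock, rose 2.09-fold (log2 fold change 1.06 ± 0.18, adjusted p = 0.0247) and 1.89-fold (0.92 ± 0.18). Bhlhe41 and Bhlhe40 (the latter outside the list), repressors within the clock, rose 2.04-fold (1.03 ± 0.20) and 1.87-fold (0.90 ± 0.16). Npas2, a partner of Arntl in the activating arm of the clock, fell 3.14-fold (-1.65 ± 0.30, 3.26 ± 1.60 against 10.2 ± 0.526 CPM). Dtna rose 1.79-fold and Glipr2 fell 1.57-fold. Of 15 clock genes 3 rose, 1 fell and 11 were not called, and 7 rose and 2 fell adjusted over the list alone (adjusted p = 0.00307, adjusted p = 0.374 with an estimated correlation). Acute-phase genes were higher as a list (median 1.14, adjusted p = 0.000202, adjusted p = 0.728 with an estimated correlation), with 0 of 14 members called and 11 higher adjusted over the list alone. B and plasma cell markers (median -0.62, adjusted p = 4.09e-05) and T and NK cell markers (-0.61, adjusted p = 0.000132) were lower as lists, with adjusted p = 0.736 and 0.786 with an estimated correlation and 0 members called. Replicate 1 stood apart from replicates 2 and 3: its acute-phase score was -0.91 against 1.79 and 1.84 (-0.54, -0.77 and 0.36 in D), its B and plasma cell score -0.10 against -1.02 and -0.74, and its T and NK cell score -0.07 against -0.86 and -0.81. Its clock score (mean of the clock genes in phase with Dbp minus that of those in phase with Arntl) was 1.85 against 0.49 and 0.14. Cxcl5 stood at 3.68 ± 3.21 CPM and was not called (log2 2.71 ± 0.82, adjusted p = 0.147).

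By the edgeR test 8 genes differed in S against D at day 1 (6 higher, 2 lower), beside 3555 at an unadjusted p under 0.05. The count was 0 without D replicate 1, 2 or 3, 505 without S replicate 1, 0 without S replicate 2 and 5 without S replicate 3. Of 7 named genes 7 lost their calls without D replicate 1, 2 or 3 or S replicate 2 and 4 without S replicate 3. DESeq2 called 190, the fit of only the groups compared 1177, the fit without a filter 31, limma on TPM 2, the fit with GC and length trends removed 23 and that with a clock score 2954.

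At day 1, L lungs differed from D lungs in 4 genes at the edgeR threshold, of which Bhlhe41 and Npas2 belong to the fixed clock list. Bhlhe41 rose 2.45-fold (log2 fold change 1.29 ± 0.20, adjusted p = 0.00668), Bhlhe40 1.97-fold (0.98 ± 0.16), and Rgs2, a brake on G-protein signalling, 2.04-fold (1.03 ± 0.17). Npas2 fell 3.10-fold (-1.63 ± 0.30, adjusted p = 0.0339). Of 15 clock genes 1 rose, 1 fell and 13 were not called, and 8 rose and 2 fell adjusted over the list alone (adjusted p = 0.000831, adjusted p = 0.275 with an estimated correlation). Interferon-stimulated genes were lower as a list of 20 (median -0.48, adjusted p = 9.75e-07), and lipid-laden or particle-laden macrophage and lysosome genes (the particle macrophage list below) were higher (median 0.22, adjusted p = 0.000106). Both had 0 members called and adjusted p = 0.733 with an estimated correlation. Neutrophil-attracting chemokines were higher as a list of 12 (median 0.38, adjusted p = 0.0159, adjusted p = 0.786 with an estimated correlation), with 0 called, either over all genes or over the list alone. They lost that call without D replicate 2 (0.26, adjusted p = 0.0906) or L replicate 2 (0.42, adjusted p = 0.118). Acute-phase genes were higher as a list of 14 (median 0.74, adjusted p = 0.000782, adjusted p = 0.733 with an estimated correlation) with 0 called, and L replicate 3 stood apart in these lists. Its acute-phase score was -0.48 against 1.03 and 1.04 in the other L libraries, its chemokine score -0.78 against 0.14 and 0.53, its interferon score -0.03 against -0.68 and -0.67 (-0.12, 0.10 and -0.05 in D), and its clock score 2.14 against 0.92 and 0.45. Neutrophil markers had a median of 0.31 (adjusted p = 0.138), and Cxcl5 stood at 0.999 ± 0.780 CPM.

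Of the 835 genes at an unadjusted p under 0.05 in L against D at day 1, edgeR thus called 3 higher and 1 lower. Leaving out D replicate 1, 2 or 3 gave 0 genes each, and leaving out L replicate 1, 2 or 3 gave 3, 5 or 1. The 4 named genes lost their calls without any 1 D library or L replicate 3, and 1 of them without L replicate 1. DESeq2 called 26, the fit without a filter 18, the fit of only the groups compared 1, that with GC and length trends removed 8 and that with a clock score 26.

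At day 7, US lungs differed from D lungs in clock genes, and in 1 gene each of the fat and the secretory airway lists. Npas2 fell 6.88-fold (log2 fold change -2.78 ± 0.32, 1.71 ± 0.592 against 11.7 ± 4.46 CPM, adjusted p = 2.5e-05). Dbp rose 4.65-fold (2.22 ± 0.50), the period genes Per2 and Per3 4.44-fold (2.15 ± 0.34) and 2.87-fold (1.52 ± 0.21), and Hlf 2.99-fold (1.58 ± 0.19). Of 15 clock genes 8 rose, 2 fell and 5 were not called, and 9 rose and 2 fell adjusted over the list alone (median 1.31, adjusted p = 4.09e-05, adjusted p = 0.111 with an estimated correlation). Bpifa1, a secreted protein of airway lining, fell 43.7-fold (-5.45 ± 1.3), from 66.8 ± 78.8 CPM in D to 1.52 ± 0.288 CPM, and Adig, a gene of fat cells, fell 2.85-fold (-1.51 ± 0.39). Of 7 fat markers 1 fell and 6 were not called, with 5 lower adjusted over the list alone (median -2.55, adjusted p = 0.000202, adjusted p = 0.473 with an estimated correlation). Of 12 club and secretory airway cell markers 1 fell and 11 were not called, with 4 lower adjusted over the list alone (median -0.38, adjusted p = 0.00784, adjusted p = 0.733 with an estimated correlation). The ciliated cell genes Dnah9, Sec14l3 and Hydin rose 1.71-, 1.63- and 1.77-fold, and the endothelial genes Egfl7 and Cldn5 fell 2.00- and 2.04-fold. Fat transcripts were high in the D lungs of that day: Adipoq stood at 2.98 ± 1.92 CPM in D and 0.325 ± 0.438 CPM in US, and Cfd at 14.3 ± 7.55 and 1.63 ± 1.53 CPM (both chosen after their values were seen).

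The edgeR test called 353 genes in US against D at day 7 (153 higher, 200 lower), beside 4352 at an unadjusted p under 0.05. Without D replicate 1, 2 or 3 the count was 18, 42 or 2224, and without US replicate 1, 2 or 3 it was 47, 3035 or 18. Hlf, Per2, Per3, Npas2 and Tef kept their calls in each of these fits. Of 29 named genes 21, 21 or 1 lost theirs without D replicate 1, 2 or 3 and 19 or 22 without US replicate 1 or 3 (Dbp, Bpifa1 and Adig with adjusted p up to 0.174, 0.246 and 0.252). DESeq2 called 1208 and the fit of only the groups compared 10. Limma on TPM called 89 higher and 40 lower, and the fit with the fat score as a covariate 99 higher and 22 lower. With the clock score as a covariate the count was 2735, and Dbp, Nr1d1 and Bpifa1 changed sign (log2 -0.84, -0.54 and 0.60).

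At day 7, S lungs carried more transcript of neutrophil-attracting and macrophage genes than D lungs. Cxcl5 rose 17.2-fold (log2 fold change 4.10 ± 0.76, 12.1 ± 8.01 against 0.702 ± 0.0995 CPM, adjusted p = 0.0103), and Ccl20, a chemokine for lymphocytes and dendritic cells, 14.7-fold (3.88 ± 0.81). Tnf, the cytokine, rose 5.80-fold (2.54 ± 0.46), and Ccl3, a chemokine made by macrophages, 3.29-fold (1.72 ± 0.31). Gpnmb rose 4.69-fold (2.23 ± 0.46) and Trem2 3.27-fold (1.71 ± 0.35). Mcidas and Ccna1, the first a regulator of multiciliated cell formation, rose 3.85- and 3.70-fold, and Klf2, a transcription factor of resting endothelium, fell 2.78-fold (-1.47 ± 0.31). Of 12 neutrophil-attracting chemokines and acute cytokines 4 rose, 0 fell and 8 were not called, with 5 higher adjusted over the list alone (median 0.76, adjusted p = 4.94e-06, adjusted p = 0.465 with an estimated correlation). Of 20 particle macrophage genes 2 rose, 0 fell and 18 were not called, with 9 higher adjusted over the list alone (median 0.57, adjusted p = 1.09e-07, adjusted p = 0.527 with an estimated correlation). Ciliated cell markers were higher as a list of 12 (median 0.40, adjusted p = 2.35e-07, adjusted p = 0.214 with an estimated correlation), and fat markers lower as a list of 7 (-1.70, adjusted p = 0.000247, adjusted p = 0.473 with an estimated correlation), with 0 members called in either. The 13 neutrophil markers themselves had 0 called members and a median of -0.10 (adjusted p = 0.922), with a median, mean and test that differed in sign. The chemokine score of replicate 1 was -0.22, against 1.08 and 1.05 in replicates 2 and 3 (-0.57, -0.30 and -0.54 in D), and the fat score of replicate 3 was 1.68, within the D range, against -0.12 and 0.58.

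In all, edgeR called 76 genes in S against D at day 7 (69 higher, 7 lower), beside 1577 at an unadjusted p under 0.05. Leaving out D replicate 1, 2 or 3 gave 0, 5 or 66 genes, and S replicate 1, 2 or 3 gave 92, 11 or 5. Of 24 named genes 24, 22 or 11 lost their calls without D replicate 1, 2 or 3 and 10, 19 or 23 without S replicate 1, 2 or 3, with adjusted p up to 0.123 for Cxcl5, 0.164 for Gpnmb and 0.134 for Trem2. DESeq2 called 167, the fit with the fat score as a covariate 231 and that with GC and length trends removed 161.

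At day 7, L lungs differed from D lungs in macrophage genes and in clock genes. Mmp12 rose 23.7-fold (log2 fold change 4.57 ± 0.49, 5.39 ± 1.62 CPM in D, adjusted p = 4.82e-06), Gpnmb 6.97-fold (2.80 ± 0.46) and Trem2 3.99-fold (2.00 ± 0.35). Of 20 particle macrophage genes 3 rose, 0 fell and 17 were not called, with 11 higher adjusted over the list alone (median 0.55, adjusted p = 4.45e-18, adjusted p = 0.17 with an estimated correlation). Their score was 0.97 in replicate 1, against 0.13 and 0.33 in replicates 2 and 3 (-0.46, -0.36 and -0.35 in D). Dbp rose 5.83-fold (2.54 ± 0.51), Bhlhe41 3.04-fold (1.60 ± 0.20) and Hlf 3.01-fold (1.59 ± 0.19), while Npas2 fell 6.06-fold (-2.60 ± 0.32) and Arntl, its partner in the clock, 4.50-fold (-2.17 ± 0.29). Of 15 clock genes 7 rose, 2 fell and 6 were not called, and 8 rose and 3 fell adjusted over the list alone (median 1.21, adjusted p = 1.94e-08). This was the list that also passed with an estimated correlation (adjusted p = 0.0293). Spon2, an extracellular matrix protein, fell 4.51-fold (-2.17 ± 0.38), and Avpr1a, a vasopressin receptor, 3.02-fold (-1.60 ± 0.32). Immediate early genes were lower as a list of 16 (median -0.51, adjusted p = 1.84e-05, adjusted p = 0.482 with an estimated correlation), and fat markers lower as a list of 7 (-1.42, adjusted p = 0.000171, adjusted p = 0.473 with an estimated correlation), the latter lost without D replicate 3 (adjusted p = 0.0539). Both lists had 0 members called.

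For L against D at day 7, edgeR called 26 genes (15 higher, 11 lower), beside 824 at an unadjusted p under 0.05. Without D replicate 2 or 3 the count was 17 or 12, and Trem2 lost its call without L replicate 1 (adjusted p = 0.118) and in 1 other fit, whereas Mmp12 and Gpnmb kept theirs in each fit without 1 library. Of 20 named genes 3, 5 or 9 lost their calls without D replicate 1, 2 or 3 (Dbp with adjusted p = 0.199 without replicate 3) and 5, 4 or 3 without L replicate 1, 2 or 3. DESeq2 called 42 and the fit with the clock score as a covariate 10, in which Dbp changed sign (log2 -0.74).

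**Figure D2:**
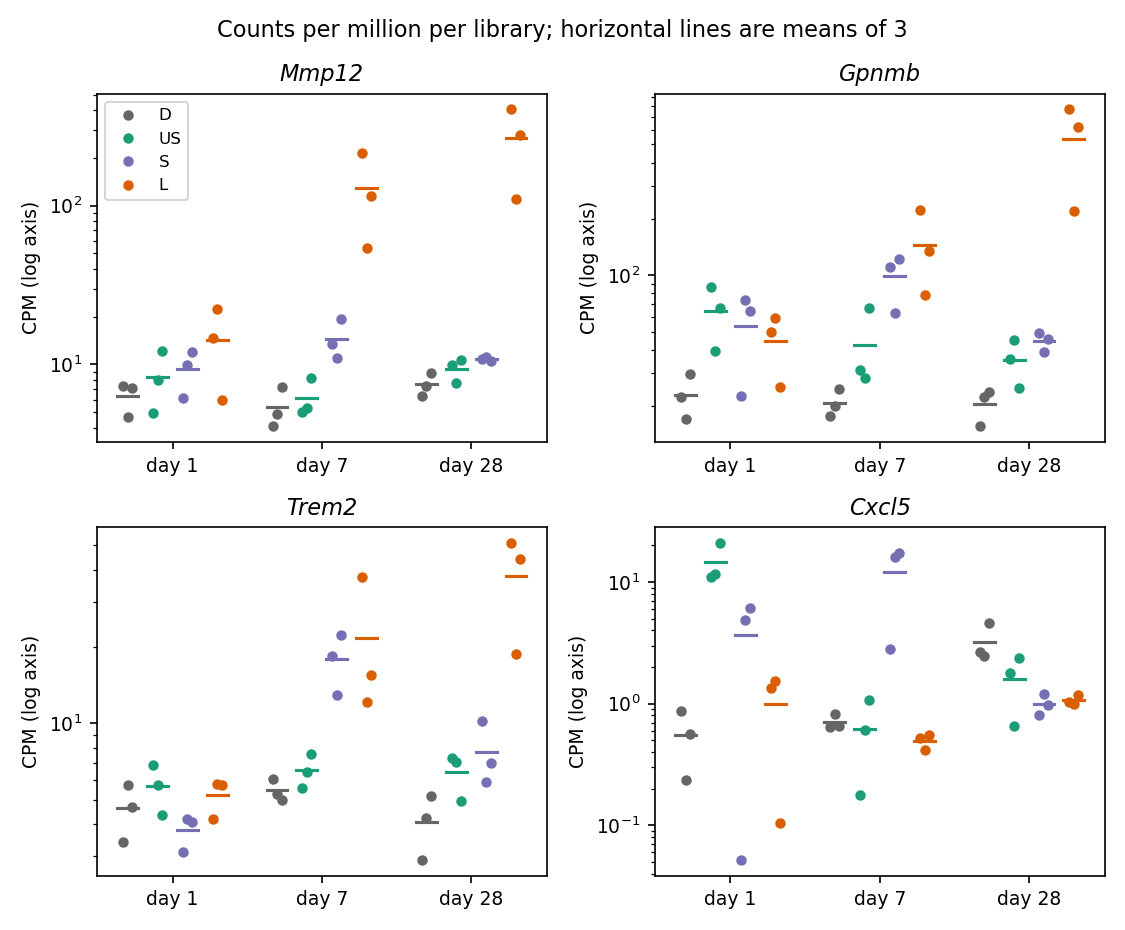
CPM (log axis) of Mmp12, Gpnmb, Trem2 and Cxcl5 in each of the 36 libraries, by material and day, where a point is a library and a line the mean of 3. L lungs reach a mean of 265 CPM of Mmp12 at day 28, against 7.52 CPM in D, and Cxcl5 is highest in US at day 1 (14.6 CPM) and S at day 7 (12.1 CPM).

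At day 28, US lungs were lower than D lungs in 4 genes and higher in 0. Dnajb1, a co-chaperone of the heat shock response, fell 2.08-fold (log2 fold change -1.06 ± 0.14, 32.3 ± 3.37 against 67.2 ± 8.15 CPM, adjusted p = 0.000364). Dusp8, a phosphatase of stress kinases, fell 2.14-fold (-1.10 ± 0.19), Pde4b, which breaks down cyclic AMP, 2.06-fold (-1.05 ± 0.17), and Bcl6b 1.77-fold (-0.82 ± 0.15). Of 10 heat shock genes 1 fell and 9 were not called, with 3 lower adjusted over the list alone (median -0.54, adjusted p = 5.9e-08, adjusted p = 0.17 with an estimated correlation). Interferon-stimulated genes were higher as a list of 20 (median 0.53, adjusted p = 5.14e-08, adjusted p = 0.728 with an estimated correlation), with 0 called and 11 higher adjusted over the list alone. That shift was in replicate 3, whose interferon score was 1.88 against 0.01 and -0.09 in the other US libraries. Without it the median was -0.09 (adjusted p = 0.304). T and NK cell markers (0.44, adjusted p = 0.000171) lost their call without the same library (adjusted p = 0.86), and had adjusted p = 0.786 with an estimated correlation.

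Of the genes in US against D at day 28, 1018 had an unadjusted p under 0.05. Leaving out US replicate 1, 2 or 3 gave 1, 10 or 1 calls by edgeR and leaving out D replicate 2 gave 2, and Dnajb1 kept its call in each fit without 1 library. Of the 4 genes 3, 2 or 1 lost their calls without D replicate 1, 2 or 3 and 3, 1 or 3 without US replicate 1, 2 or 3 (adjusted p up to 0.158 for Dusp8, 0.143 for Pde4b and 0.217 for Bcl6b). DESeq2 called 29, the fit without a filter 11, the fit of only the groups compared 8, limma on TPM 2 and the fit with a clock score 9.

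At day 28, S lungs differed from D lungs in clock and heat shock genes. Nr1d1, Nr1d2, Cry1 and Dnajb1 among them also differed between D lungs of days 28 and 1. Nr1d1 and Nr1d2, repressors of Arntl, rose 7.38-fold (log2 fold change 2.88 ± 0.39, 14.6 ± 2.30 CPM in D, adjusted p = 0.00016) and 3.07-fold (1.62 ± 0.21), and Cry1 fell 2.49-fold (-1.32 ± 0.19). Of 15 clock genes 3 rose, 1 fell and 11 were not called, and 4 rose and 5 fell adjusted over the list alone (median -0.30, adjusted p = 0.731, with a median, mean and test that differed in sign). Hspa8 (ENSMUSG00000015656, chromosome 9, 40800984 to 40805200), the constitutive heat shock protein 70, fell 2.32-fold (-1.22 ± 0.16, 846 ± 44.7 against 1970 ± 230 CPM), Hsph1 2.92-fold (-1.55 ± 0.27) and Dnajb1 2.09-fold (-1.06 ± 0.14). Of 10 heat shock genes 3 fell and 7 were not called, with 5 lower adjusted over the list alone (median -0.80, adjusted p = 1.7e-12, adjusted p = 0.0676 with an estimated correlation). Fabp4, a fatty acid carrier, rose 2.93-fold (1.55 ± 0.29), and Npr3, a receptor that clears natriuretic peptides, and Klf4 fell 2.45- and 2.39-fold. Tsc22d3, induced by glucocorticoids, fell 2.20-fold (-1.14 ± 0.25). The particle macrophage list was higher (median 0.40, adjusted p = 4.33e-06, adjusted p = 0.728 with an estimated correlation) with 0 of 20 members called, and B and plasma cell markers were higher as a list of 16 (0.56, adjusted p = 8.59e-07, adjusted p = 0.728 with an estimated correlation) with 0 called. Thymocyte markers, which thymus or mediastinal tissue would bring, were higher too as a list of 5 (0.49, adjusted p = 0.0291, adjusted p = 0.473 with an estimated correlation) with 0 called, a call lost without D replicate 1 (0.51, adjusted p = 0.128) or S replicate 1 (0.55, adjusted p = 0.0619). Their scores were 0.97, 0.66 and 0.45 in S and -0.25, 0.11 and -0.03 in D.

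At day 28, edgeR called 40 genes in S against D (15 higher, 25 lower), beside 1668 at an unadjusted p under 0.05. Without D replicate 2 or 3 the count was 17 or 21, and without S replicate 2 or 3 it was 12 each. Nr1d1, Nr1d2, Cry1, Hspa8 and Dnajb1 kept their calls in each fit without 1 library. Of 20 named genes 8, 9 or 9 lost their calls without D replicate 1, 2 or 3 and 6, 10 or 10 without S replicate 1, 2 or 3 (Fabp4 with adjusted p up to 0.122, Klf4 0.123, Npr3 0.0843, Tsc22d3 0.194, and Hsph1 0.0529 without S replicate 2). DESeq2 called 142, the fit with GC and length trends removed 95, limma on TPM 22 and the fit with the clock score as a covariate 23.

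At day 28, L lungs carried far more transcript of macrophage genes than D lungs. Mmp12 rose 35.2-fold (log2 fold change 5.14 ± 0.49, 265 ± 148 against 7.52 ± 1.27 CPM, adjusted p = 1.86e-07), Gpnmb 26.1-fold (4.70 ± 0.50, 536 ± 283 against 20.5 ± 4.31 CPM) and Trem2 9.26-fold (3.21 ± 0.36). Of 20 particle macrophage genes 13 rose, 0 fell and 7 were not called, with 17 higher adjusted over the list alone (median 0.99, adjusted p = 4.32e-23, adjusted p = 0.106 with an estimated correlation). Of 14 alveolar macrophage identity markers 1 rose, Atp6v0d2 at 2.51-fold (1.33 ± 0.26), 0 fell and 13 were not called (median 0.01, adjusted p = 0.727). Cxcr1, a receptor for neutrophil chemokines, rose 8.71-fold (3.12 ± 0.48), Ccl3 2.94-fold (1.56 ± 0.32) and Fabp4 4.55-fold (2.19 ± 0.29). Jchain and Igkc, which encode immunoglobulin chains, rose 3.03-fold (1.60 ± 0.39) and 2.07-fold (1.05 ± 0.28). Of 16 B and plasma cell markers these 2 rose and 14 were not called, with 10 higher adjusted over the list alone (median 0.62, adjusted p = 4.3e-07, adjusted p = 0.728 with an estimated correlation). Of 10 heat shock genes 5 fell and 5 were not called, with 6 lower adjusted over the list alone (median -0.91, adjusted p = 6.14e-10, adjusted p = 0.106 with an estimated correlation), Hspa8 by 2.41-fold (-1.27 ± 0.16) and Hsph1 by 3.48-fold (-1.80 ± 0.27).

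Clock genes also differed in L at day 28, when D itself had moved (clock score -0.22 at day 1, -2.22 at day 28, 0.60 in L). Dbp rose 17.5-fold (log2 fold change 4.13 ± 0.59, 61.5 ± 14.8 against 3.50 ± 0.440 CPM) and Nr1d1 14.3-fold (3.83 ± 0.40), and Npas2 and Arntl fell 3.71-fold (-1.89 ± 0.29) and 3.16-fold (-1.66 ± 0.27). Of the 15 clock genes 7 rose, 5 fell and 3 were not called (7 and 6 adjusted over the list alone). With members on both sides, the list had a median of 0.16 (adjusted p = 0.228). Cd163l1, Tcrg-C1 and Trdc, genes of γδ T cells (the last 2 are receptor segments whose reads can be shared with related copies), fell 6.75-, 3.66- and 2.97-fold against D values of 12.1 ± 16, 9.54 ± 10.3 and 10.6 ± 10.7 CPM, and lost their calls without D replicate 3 (adjusted p = 0.545, 0.556 and 0.686).

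The edgeR test called 363 genes in L against D at day 28 (212 higher, 151 lower; 235 and 268 with GC and length trends removed), beside 2829 at an unadjusted p under 0.05. Without D replicate 1, 2 or 3 the count was 179, 150 or 206, while 72 genes were higher and 40 lower without L replicate 1, and 77 and 30 without L replicate 3. Mmp12, Gpnmb, Trem2, Dbp, Nr1d1, Npas2, Hspa8 and Hsph1 kept their calls in each fit without 1 library. Of 30 named genes 5, 7 or 9 lost theirs without D replicate 1, 2 or 3 and 11, 2 or 10 without L replicate 1, 2 or 3, Jchain and Igkc in 5 of the 6 fits (adjusted p up to 0.16 and 0.196) and Ccl3 without D replicate 3 (0.0511). The fit of only the groups compared called 805, limma on TPM 148, and the fit with the clock score as a covariate 12. In the last, Npas2 and Arntl changed sign (log2 0.28 and 0.39) and Trem2 lost its call (adjusted p = 0.0605, from 2.27e-17 to 0.0605 over its alternatives).

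**Figure D3:**
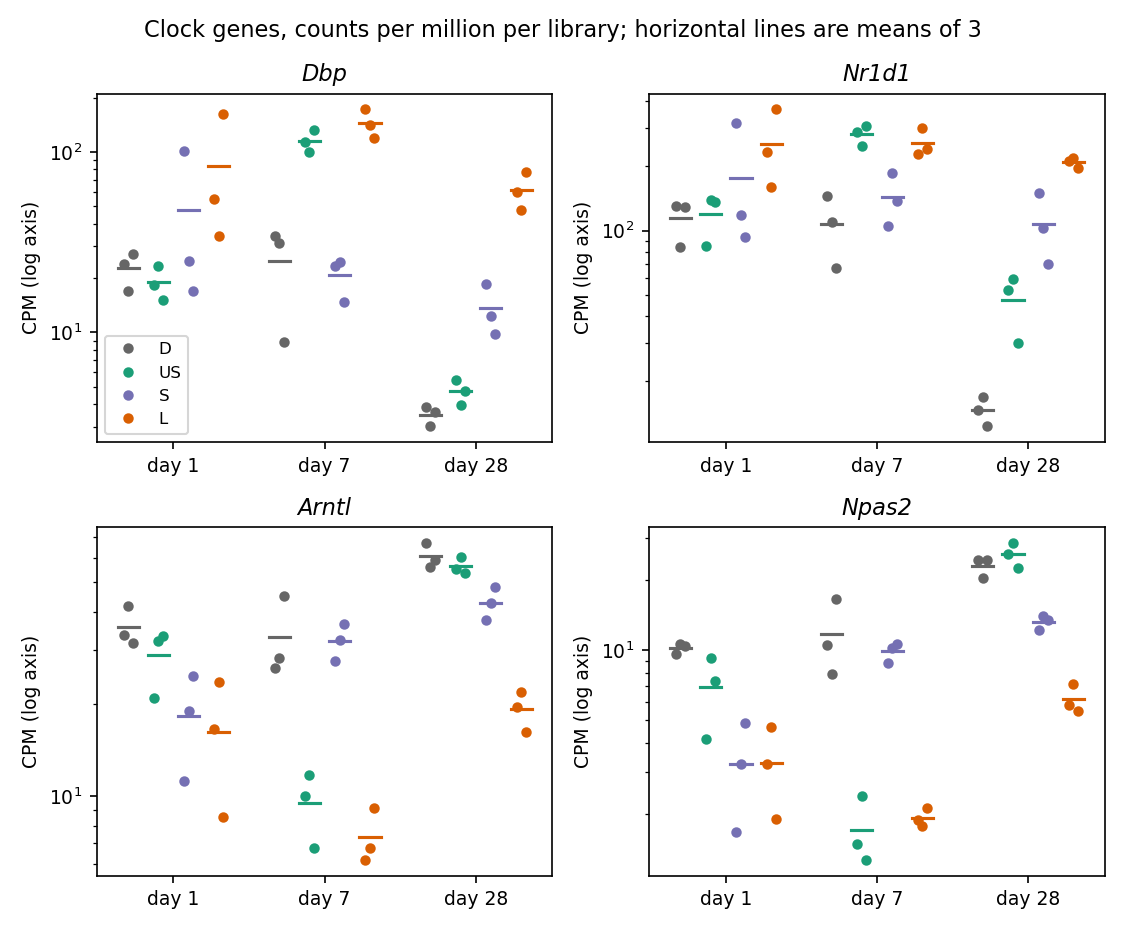
CPM (log axis) of Dbp, Nr1d1, Arntl and Npas2 in each of the 36 libraries, by material and day, where a point is a library and a line the mean of 3. D lungs at day 28 hold a mean of 3.50 CPM of Dbp and 14.6 CPM of Nr1d1 (7.88-fold below day 1), against 61.5 and 208 CPM in L lungs.

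Sizes were compared with each other within each day, which addresses directly whether lateral size matters. At day 1 the edgeR test called 0 genes between L and US (1060 at an unadjusted p under 0.05; DESeq2 called 19, the fit of only the groups compared 0 and limma on TPM 0) and 0 between L and S (1759 unadjusted; DESeq2, the fit of only the groups compared and limma 0). In S against US it called 3 of 2315 unadjusted: Fbxo32, a ubiquitin ligase, was 1.82-fold higher in S (log2 fold change 0.86 ± 0.15). Bysl and Glipr2 were 1.78- and 1.66-fold lower (-0.83 ± 0.13 and -0.73 ± 0.11). The 3 lost their calls without S replicate 1 (adjusted p up to 0.0932), and Fbxo32 in 4 of the 6 fits without 1 library. Neutrophil-attracting chemokines were lower in L than US as a list of 12 (median -0.54, adjusted p = 2.51e-07, adjusted p = 0.674 with an estimated correlation), with 0 called and 5 lower adjusted over the list alone. Neutrophil markers were lower in L than US (-0.86, adjusted p = 1.32e-06) and in S than US (-1.03, adjusted p = 7.72e-07), each with 0 called and adjusted p = 0.674 with an estimated correlation. Without US replicate 1 the former list missed the threshold (adjusted p = 0.156). L against US gave 9 genes without US replicate 2, and 1 without US replicate 1 or L replicate 2. S against US gave 12, 5 or 30 genes without US replicate 1, 2 or 3 and 1 or 2 without S replicate 1 or 2. DESeq2 called 40 higher and 87 lower in S against US.

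At day 7, Mmp12 was 20.8-fold higher in L than in US lungs (log2 fold change 4.38 ± 0.48, adjusted p = 8.48e-06) and 8.92-fold higher in L than in S lungs (3.16 ± 0.44, adjusted p = 0.000303). It was the 1 gene called by edgeR in L against US. Cxcl5 was 19.6-fold higher in S than in US (4.30 ± 0.77) and 24.1-fold lower in L than in S (-4.59 ± 0.80). Of 12 neutrophil-attracting chemokines and acute cytokines 1 was lower in L than S and 11 were not called, with 7 lower adjusted over the list alone (median -1.05, adjusted p = 7.05e-07, adjusted p = 0.674 with an estimated correlation). The clock genes set S apart from both other sizes: Dbp was 6.89-fold higher in L than in S (2.78 ± 0.51) and 5.49-fold lower in S than in US (-2.46 ± 0.50), and Npas2 was 5.13-fold lower in L than in S (-2.36 ± 0.32) and 5.83-fold higher in S than in US (2.54 ± 0.32). Of 20 particle macrophage genes 1 was higher in L than US and 19 were not called, with 7 adjusted over the list alone (median 0.38, adjusted p = 1.29e-06, adjusted p = 0.7 with an estimated correlation). Of 15 clock genes 5 were higher and 2 lower in L than S (8 and 3 adjusted over the list alone, adjusted p = 6.87e-05, adjusted p = 0.177 with an estimated correlation), and 2 higher and 6 lower in S than US (3 and 9 adjusted over the list alone, adjusted p = 2.28e-05, adjusted p = 0.177 with an estimated correlation).

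The edgeR counts at day 7 were 1 for L against US, 26 for L against S (13 higher, 13 lower) and 24 for S against US (11 higher, 13 lower). Without US replicate 2 they were 5 for L against US and 75 for S against US, without US replicate 1 or 3 S against US gave 11 or 12, and without S replicate 2 or 3 it gave 12 or 14. L against US gave 3 without L replicate 2 and 862 without L replicate 3, and L against S gave 14 without S replicate 2 or 3 or L replicate 1, and 13 without L replicate 2. Mmp12 kept its call in each of these fits, while Cxcl5 lost its call in S against US without US replicate 1 (adjusted p = 0.0918). In L against S it lost its call without L replicate 2 (adjusted p = 0.0655) and in 1 other fit. Dbp lost its call in 2 of 6 fits of L against S (adjusted p up to 0.119, without S replicate 3) and in 5 of S against US (up to 0.27, without S replicate 3). DESeq2 called 3, 58 and 90, the fit of only the groups compared 0, 22 and 9, and thinning S day 7 replicate 2 gave 16 for L against S.

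At day 28, macrophage genes were higher in L than in both smaller sizes. Mmp12 was 28.3-fold higher in L than in US (log2 fold change 4.82 ± 0.48, adjusted p = 8.97e-07) and 24.5-fold higher than in S (4.62 ± 0.48, adjusted p = 2.02e-06). Gpnmb was 15.2-fold (3.93 ± 0.48) and 12.0-fold (3.59 ± 0.47) higher, and Trem2 5.92-fold (2.57 ± 0.35) and 4.93-fold (2.30 ± 0.34). Mfge8, a bridge protein for the uptake of dying cells, was 2.63-fold higher in L than in S (1.39 ± 0.20), and Hk3, a hexokinase of myeloid cells, 2.83-fold (1.5 ± 0.26). Of 20 particle macrophage genes 10 were higher in L than US and 10 were not called, with 14 adjusted over the list alone (median 0.79, adjusted p = 3.68e-21, adjusted p = 0.177 with an estimated correlation). In L against S 3 were higher and 17 not called, with 12 adjusted over the list alone (0.58, adjusted p = 2.29e-27, adjusted p = 0.177 with an estimated correlation). Dbp was 13.0-fold higher (3.70 ± 0.56) and Npas2 4.14-fold lower (-2.05 ± 0.29) in L than US. B and plasma cell markers were higher as a list in L than US (0.57, adjusted p = 1.05e-08) and in S than US (0.51, adjusted p = 4.38e-09), with adjusted p = 0.698 with an estimated correlation in both and 0 members called. Thymocyte markers were also higher in S than US (0.56, adjusted p = 0.0202, adjusted p = 0.674 with an estimated correlation), with 0 called, and lost that call without US replicate 1 or 2 or S replicate 1 (adjusted p up to 0.0745).

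At day 28, edgeR called 87 genes in L against US (59 higher, 28 lower), 11 in L against S (11 higher, 0 lower) and 0 in S against US (920 at an unadjusted p under 0.05; DESeq2 called 7, the fit of only the groups compared 0 and limma on TPM 0). L against US gave 47 without US replicate 1, and 29, 151 or 29 without L replicate 1, 2 or 3. L against S gave 6, 5 or 7 without S replicate 1, 2 or 3 and 6, 64 or 7 without L replicate 1, 2 or 3, and S against US gave 3 without US replicate 1 or 2 or S replicate 1. Mmp12, Gpnmb and Trem2 kept their calls in each of these fits. Hk3 lost its call in 3 (adjusted p up to 0.138, without L replicate 1). DESeq2 called 185 and 32 in L against US and L against S, limma on TPM 39 and 5, and the fit without a filter 33 in L against S.

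**Figure D4:**
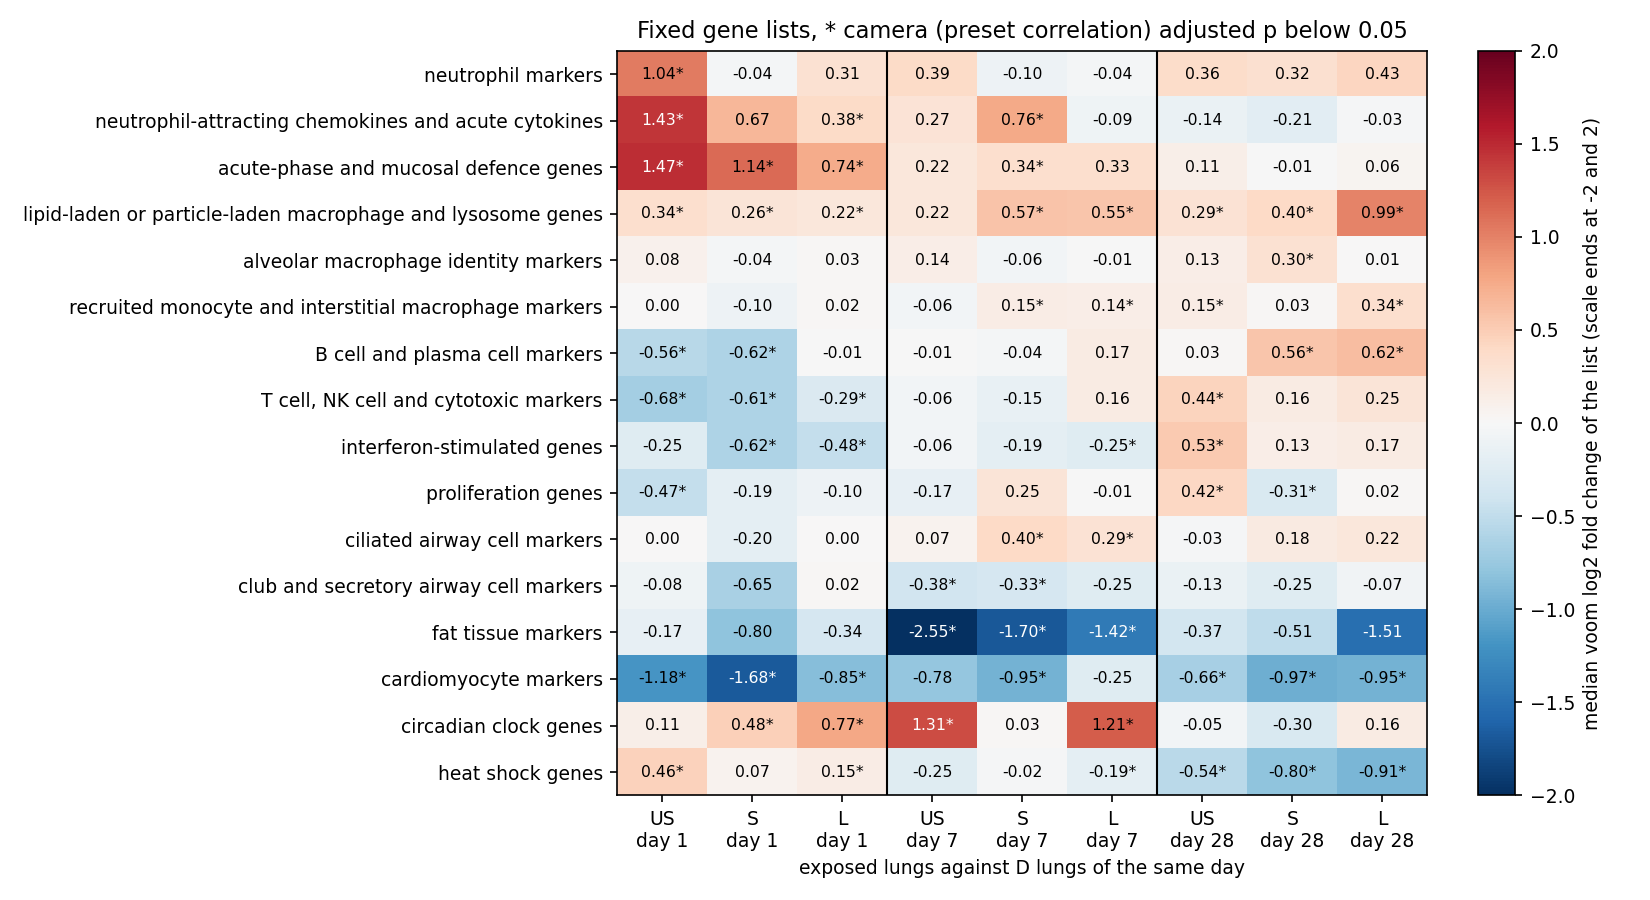
Median voom log2 fold change of 16 fixed gene lists (vertical) in the 9 comparisons of exposed with D lungs (horizontal), with colour running from -2 to 2 and a star where camera at its preset correlation gave an adjusted p below 0.05. The particle macrophage list has medians of 0.55 and 0.99 in L lungs at days 7 and 28, and the heat shock list medians of -0.54, -0.80 and -0.91 in US, S and L lungs at day 28.

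Effects of the sizes were compared gene by gene over all tested genes, which are not independent. The correlation of the L and S effects at day 28 was 0.67, against 0.50 simulated for unchanged groups that share the same D libraries, and the covariance exceeded the simulated one by 0.0571. These lists of calls shared 12 higher and 21 lower genes, where independent lists would share 0.188 and 0.223. The L and US effects at day 28 correlated at 0.49 against 0.51 simulated, with a covariance difference of 0.0216, and shared 0 higher and 3 lower genes (0 and 0.0357 for independent lists). Those of S and US at day 28 correlated at 0.55 against 0.51 simulated, with a covariance difference of 0.0173, and shared 0 higher and 3 lower genes (0 and 0.00592 for independent lists). At day 1 the correlations were 0.67 (L and US), 0.62 (L and S) and 0.67 (S and US), against 0.52, 0.51 and 0.51 simulated, with covariance differences of 0.0508, 0.0468 and 0.0895. At day 7 they were 0.60, 0.60 and 0.66 against 0.51, 0.53 and 0.53, with differences of 0.0407, 0.0220 and 0.0589. Among genes with a mean of at least 10 CPM the covariance fell below the simulated one for L and S at day 7 (difference -0.00915, correlation 0.50 against 0.52) and for L and US and S and US at day 28 (-0.00161 and -0.0064). At day 7, L and US shared 10 higher and 10 lower genes (0.136 and 0.130 for independent lists), S and US 19 and 2 (0.625 and 0.0828), and L and S 3 and 0 (0.0612 and 0.00456). With 3 D libraries per day the controls could not be split. The excess may come from them or from sample structure that the simulation may lack.

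Whether the effect of a size changed between days 1 and 28 was tested as an interaction. For US, the Cxcl5 effect was 52.6-fold lower at day 28 than at day 1 (log2 difference -5.72 ± 1.06, adjusted p = 0.0371), and the effects on Hspa8 and Dnajb1 2.45- and 2.44-fold lower (-1.29 ± 0.23 and -1.29 ± 0.20). For S, those on Cry1 and Hspa8 were 3.58-fold (-1.84 ± 0.27) and 3.03-fold lower (-1.60 ± 0.23). For L, the effects on Mmp12, Gpnmb and Trem2 were 15.7-fold (3.97 ± 0.65, adjusted p = 0.0062), 13.4-fold (3.74 ± 0.64) and 8.20-fold higher (3.04 ± 0.51) at day 28. The edgeR counts were 8 for US (3 higher, 5 lower), 33 for S (6 and 27) and 41 for L (19 and 22). Mmp12, Gpnmb and Trem2 for L, and Cry1 and Hspa8 for S, kept their calls in each fit without 1 library. Cxcl5 for US lost its call in 9 of 12 (adjusted p up to 0.145, without D day 1 replicate 2).

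The interaction count for US, 8 with all libraries, was 4, 0 or 1 without D day 1 replicate 1, 2 or 3, and 92 or 2 without US day 1 replicate 2 or 3. It was 1 or 3 without D day 28 replicate 2 or 3, and 1, 3 or 2 without US day 28 replicate 1, 2 or 3. For S, 33 became 11, 3 or 7 without D day 1 replicate 1, 2 or 3, 318, 7 or 6 without those of S day 1, 6, 5 or 8 without those of D day 28, and 11, 4 or 7 without those of S day 28. For L, 41 became 16, 9 or 8 without D day 1 replicate 1, 2 or 3, 7, 11 or 318 without those of L day 1, 17 or 13 without D day 28 replicate 1 or 2, and 13, 76 or 10 without those of L day 28. DESeq2 called 70, 384 and 98, the fit of only the groups compared 5, 2624 and 9, and limma on TPM 2, 7 and 20.

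D lungs were also compared between days. Between days 1 and 28, Nr1d1 fell 7.88-fold (log2 fold change -2.98 ± 0.39, to 14.6 ± 2.30 CPM, adjusted p = 0.000181) and Nr1d2 4.07-fold (-2.03 ± 0.22), and Cry1 rose 2.52-fold (1.33 ± 0.19). Slc4a1, the anion exchanger of red blood cells, rose 5.63-fold (2.49 ± 0.50) and Dnajb1 1.68-fold (0.75 ± 0.14). Of 10 heat shock genes 1 rose and 9 were not called, with 4 higher adjusted over the list alone (median 0.58, adjusted p = 3.44e-11, adjusted p = 0.0545 with an estimated correlation). The comparisons of US, S and L with D at day 28, and the interactions, rest on these same D libraries. A rise of heat shock genes and Cry1 in D and a fall in exposed lungs cannot be told apart there. Between days 1 and 7 the fat list was higher (median 3.46, adjusted p = 9.07e-05, adjusted p = 0.472 with an estimated correlation), with 0 of 7 members called and 6 higher adjusted over the list alone.

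Between D at days 28 and 1, edgeR called 13 genes (9 higher, 4 lower), and 5, 5 or 3 without D day 1 replicate 1, 2 or 3 and 5, 7 or 5 without D day 28 replicate 1, 2 or 3. Nr1d1, Nr1d2 and Cry1 kept their calls in each of these fits. Slc4a1 lost its call in each (adjusted p up to 0.372) and Dnajb1 in 4 (up to 0.251). DESeq2 called 29, the fit of only the groups compared 76 and limma on TPM 6. The edgeR count was 0 between days 7 and 1 (4085 at an unadjusted p under 0.05; DESeq2 called 60, the fit of only the groups compared 69 and limma on TPM 1), and 1691 without D day 7 replicate 3.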

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

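The tests of clock genes, those of the first principal component alone and of the fat score on the calls of US against D at day 7, and those regrouping 2 groups of 3 libraries were chosen only after the result was seen, as were the alternatives with GC and length trends removed, a fat score or a clock score, or S day 7 replicate 2 thinned. The tests of macrophage genes, of depth, of other tissue along the first component and of the regrouped interactions were chosen before.

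Genes stand here because edgeR called the effect of a size different between days 28 and 1 (log2 difference, day 28 minus day 1). For US, 8 genes differed. The effect on Cxcl5 was lower by a log2 difference of -5.72, those on Dusp8, Hspa8 and Dnajb1 by -1.57, -1.29 and -1.29, and those on 0610040B10Rik, Adck3 and Accs were higher by 2.27, 1.14 and 1.06. Without D day 1 replicate 2 each of these 7 named genes lost its call (adjusted p up to 0.181). For S, 33 genes differed, among them Igkv4-72 (4.06), A430027H14Rik (2.33), 0610040B10Rik (2.28), Slc14a1 (1.52) and Lrrc29 (1.40) upward and Per2 (-2.20), Cry1 (-1.84), Hsph1 (-1.76), Gm15459 (-1.75) and Hspa8 (-1.60) downward. Cry1 and Hspa8 kept their calls in each fit without 1 library, Gm15459 lost its call in 4 of 12 (adjusted p up to 0.0675, without D day 1 replicate 2), 0610040B10Rik in 7, and the other 6 in 9 to 11. Reads of Igkv4-72 can be shared with related immunoglobulin segments, and those of Gm15459 and the unnamed transcripts with overlapping or similar genes, so these values are uncertain.

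For L, 41 genes differed, among them Mmp12 (3.97), Gpnmb (3.74), Trem2 (3.04), Nr1d1 (2.70) and Fam83f (2.10) upward and Dclk3 (-2.16), Arsi (-2.02), Hsph1 (-1.98), Gm15459 (-1.70) and Cry1 (-1.54) downward. Mmp12, Gpnmb, Trem2 and Cry1 kept their calls in each fit without 1 library. Nr1d1, Hsph1 and Gm15459 lost theirs in 5, 6 and 2 of 12, each with its highest adjusted p without L day 1 replicate 1 (0.0821, 0.0987 and 0.0821), as did Dclk3 in 10 (0.139). Fam83f lost its call in 9 (up to 0.185, without L day 28 replicate 3) and Arsi in 7 (up to 0.109, without D day 28 replicate 2).

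Over 100 splits of the 12 libraries of each interaction, as many genes were called in 3 for US (8 genes in the real split, at most 12 in another), 2 for S (33 and 1.0e2) and 8 for L (41 and 185). Chance is not excluded by these shares, unadjusted over the 3 interactions. Without D day 1 replicate 2 the numbers of US and S fell to 0 and 3. For S and L some splits called several times the real number. They may keep part of the real groups, so the cause stays open.

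Clock genes differed between exposed and D lungs of the same day. In the comparisons with at least 8 of 15 clock genes called (US and L at day 7, L at day 28) at least 13 lay on the side given by their phase, and 3 clock genes were called between D lungs of days 28 and 1, so tissue collected at different times of day is a candidate explanation there. The restriction to at least 8 called genes came after S at day 1 had shown 10 on that side. The first-written bound would have taken that as excluding the explanation. The condition that fits without 1 library (8 to 11) also meet the bound came later too, and S at day 1 is left open. With the fat score, 9 of 10 called clock genes in US and 8 of 9 in L at day 7 stayed called. Fat scores of D and US do not overlap and only L replicate 1 reached the D range, so fat in D stays open. A shift by the sheets in one order of sizes is argued against, since the clock score of US minus S was 2.34 at day 7 and -0.93 at day 28. Other cell types cannot be told apart, because the lowest ratio of a phase median to its SD over members was 0.536, and a direct effect of the sheets on the clock stays open, as the hours of collection are not given in the sources used here.

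The first principal component held 30.8% of the variance across libraries, and US against D at day 7 gave 353 calls. Across 36 libraries the component correlated with the skeletal muscle list (4 measured members), the highest of 4 tissue lists (rho 0.617). Without listed genes rho was 0.616 and r 0.619, and r was 0.61 without the 2 farthest libraries. Libraries of a group or day are not independent, so no p-value is given. Within days rho was 0.909, 0.322 and -0.217 at days 1, 7 and 28, so the relation held at day 1 and not within days 7 and 28, and other tissue is a candidate explanation for the component over all days and at day 1. With the fat score 99 genes were higher and 22 lower (1.2e2 in all, 72 of them among the 353). This score itself separates the groups (1.84, 1.22 and 2.64 in D, -0.34, -0.75 and 0.90 in US). Its slope comes from the spread within groups, so fat in the D lungs and an effect of US cannot be told apart. Across genes, which are not independent, loadings had rho -0.555 with transcript length and 0.326 with GC content; with both trends removed 399 genes were called (141 higher and 258 lower, against 153 and 200), 233 of them among the 353, which argues against these trends as the whole cause and leaves them open for the calls that were lost, while depth cannot be told apart, with rho -0.169 (SE 0.174) over all days and -0.245, -0.476 and -0.385 within days.

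Macrophage genes were higher in L than D lungs at day 28. More macrophages of the resident kind are argued against by the edgeR medians of 0.02 for the alveolar macrophage list and 1.04 for the particle macrophage list (the first minus 0.5 of the second was -0.50, with an interquartile range of 0.19). Fat, heart or thymus tissue in the L libraries is argued against because 0 of the fat, cardiomyocyte and thymus lists were raised, whereas the upper airway gland list (4 measured members) was not tested. Mmp12, Gpnmb and Trem2 had an adjusted p of at most 0.000161 over the fits without 1 library. That shows only that their calls did not rest on a single library, and not which tissue the libraries held. Time of collection is argued against by an adjusted p of at most 0.000713 for the same genes in L against US and S, though less firmly than that value reads, since L also differed from them in clock score (0.60 against -1.98 and -1.05); US at day 7 had a clock shift of 2.44 with Mmp12 at 6.18 ± 1.80 CPM, and with the clock score as a covariate Mmp12 kept its call (log2 7.13, adjusted p = 8.9e-06, alternatives 2.39e-24 to 0.000666), as did Gpnmb (5.98, 0.000864, alternatives 3.22e-20 to 0.000864), but not Trem2 (3.16, 0.0605, alternatives 2.27e-17 to 0.0605). A change of macrophages with large sheets stays a hypothesis, found and tested on the same data.

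Splits of 2 groups of 3 libraries number 10, too few for a share under 0.05. Against D at day 1 the real split called 15, 8 and 4 genes (US, S and L) and the highest other 0, 4 and 0, with 1 of 10 splits as large each. At day 7 it called 353, 76 and 26 against 3104, 0 and 485, with 2, 1 and 2 as large, and at day 28 it called 4, 40 and 363 against 2, 0 and 7, with 1 each. Between sizes at day 1 it called 0, 0 and 3 (L against US, L against S, S against US) and the highest other 172, 143 and 917, with 10, 10 and 2 as large. At day 7 it called 1, 26 and 24 against 3807, 0 and 0 (2, 1 and 1 as large), and at day 28 87, 11 and 0 against 22, 1 and 0 (1, 1 and 10 as large). Between D lungs it called 0 for days 7 and 1 and 13 for days 28 and 1, against 0 and 0 (10 and 1 as large). The high counts of other splits for US and L at day 7 against D, for L against US at days 1 and 7, and for L against S and S against US at day 1 point to a structure of the samples that the groups do not give.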

How the results depend on the processing

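Alternatives with GC and length trends removed, a fat or clock score or thinning were chosen after seeing the data, and all others before. With DESeq2's size factors in edgeR, each of the 25 counts of genes or lists stayed within 1.5 times its value and 224 of 225 calls of named genes held. Counts by the other settings moved as follows, and the cause was not tested where none is given. The calls of Mmp12, Gpnmb and Trem2 in L against D at day 28 held except for that of Trem2 with the clock score. With S day 7 replicate 2 thinned to the median total of the others, L against S at day 7 gave 16 calls in place of 26, and S against D and S against US at day 7 gave 64 and 24, within 1.5 times. At the other libraries' depth 1 CPM is 16.2 to 23.8 counts, which limits what could be called among weakly expressed genes.

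Without a filter on low counts, US, S and L against D at day 1 gave 137, 31 and 18 genes, US at day 28 gave 11, L against US at days 1 and 7 gave 2 and 3, L against S at day 28 gave 33, and D at day 7 against day 1 gave 14. With GC and length trends removed, US, S and L against D at day 1 gave 448, 23 and 8, and S gave 161 at day 7 (48 of them lower, against 7 of 76) and 95 at day 28. L gave 503 at day 28, where lower genes became the larger part (235 higher and 268 lower, against 212 and 151). With the fat score, US and S against D at day 7 gave 99 higher and 22 lower (1.2e2 in all) and 231. Fat scores of US and D at day 7 do not overlap. The slope comes from the spread within groups, so the correction reaches beyond any shared scores.

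With the clock score, US, S and L against D gave 141, 2954 and 26 at day 1, US and L gave 2735 and 10 at day 7, and US, S and L gave 9, 23 and 12 at day 28. In that fit Dbp (log2 -0.84), Nr1d1 (-0.54) and Bpifa1 (0.60) changed sign in US against D at day 7. So did Dbp (-0.74) and 5430416O09Rik (0.01) in L at day 7, and Npas2 (0.28) and Arntl (0.39) in L at day 28. The clock score is built from clock genes and differs between groups. These fits take its slope from the spread within groups and shift each group difference by it. Why counts rose or fell was not tested.

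DESeq2 gave 347, 190 and 26 genes for US, S and L against D at day 1, 1208, 167 and 42 at day 7, and 29 and 142 for US and S at day 28. Between sizes it gave 19 for L against US and 40 higher and 87 lower (1.3e2 in all) for S against US at day 1, and 3, 58 and 90 for L against US, L against S and S against US at day 7. At day 28 it gave 185, 32 and 7. For the effects of US, S and L at day 28 against day 1 it gave 70, 384 and 98, and for D at days 7 and 28 against day 1 60 and 29.

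With only the groups compared in the fit, US, S and L against D at day 1 gave 2, 1177 and 1, US gave 10 at day 7 and 8 at day 28, and L gave 805 at day 28. S against US at day 1 and L against US at day 7 gave 0 (edgeR with all libraries called 3 and 1, from 2315 and 2534 at an unadjusted p under 0.05, and DESeq2 the numbers above), and S against US at day 7 gave 9. The effects of US, S and L at day 28 against day 1 gave 5, 2624 and 9, and D at days 7 and 28 against day 1 gave 69 and 76. Such fits estimate the spread from fewer libraries.

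Limma on log2(TPM + 1) gave 1 and 2 genes for US and S against D at day 1, 89 higher and 40 lower (1.3e2 in all) for US at day 7, and 2, 22 and 148 for US, S and L at day 28. It gave 0 for S against US at day 1, 39 and 5 for L against US and L against S at day 28, 2, 7 and 20 for the effects of US, S and L at day 28 against day 1, and 1 and 6 for D at days 7 and 28 against day 1. The correlations of effects by it were 0.56 (L and S) and 0.60 (S and US) at day 1, 0.52 (L and S) at day 7 and 0.70 (L and S) at day 28. At a mean of at least 10 CPM they were 0.71 (L and US), 0.59 (L and S) and 0.60 (S and US) at day 1, 0.50 (L and S) at day 7, and 0.79 (L and S) and 0.59 (S and US) at day 28. The values simulated at that mean were 0.52, 0.51 and 0.51 at day 1, 0.52 at day 7, and 0.50 and 0.51 at day 28, so L and S at day 7 fell below theirs. For TPM no such value was simulated.

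Replicate numbers did not pair the libraries: of 54 correlations between same-numbered libraries 11 exceeded 0.1 (-0.4769 to 0.3709). With the replicate block, US and S against D gave 4 and 3 genes at day 1, US gave 194 at day 7 (89 of them lower, against 200 of 353, so higher genes became the larger part), and S and L gave 25 and 196 at day 28. L against S at day 28 gave 7, the effects of US, S and L at day 28 against day 1 gave 2, 4 and 17, and D at day 28 against day 1 gave 3. Of 159 list calls 155 held with it, and the other counts stayed within 1.5 times.

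Camera with an estimated correlation called 1 list against D and 0 between sizes, and fry called 10 and 4, in place of 89 and 70 by camera at its preset correlation. Of 225 calls of named genes or of the fewer a setting covers, DESeq2 ended 1, no filter 13, GC and length trends 9, the fat score 27, the clock score 60, the block 64, TPM 80, only the groups compared 85 and thinning 3, none of them turning sign apart from the 7 under the clock score. The larger part of the calls, higher or lower, also turned for S at day 1 (1407 and 1547) and L at day 7 (3 and 7) with the clock score, for S at day 1 with the block (1 and 2), for L at day 1 with only the groups compared (0 and 1), and for S against US at day 7 without a filter (21 and 13). It turned for the L effect at day 28 against day 1 with the block, only the groups compared and TPM (9 and 8, 6 and 3, 12 and 8), and for D at day 28 against day 1 without a filter, with the block, only the groups compared and TPM (6 and 7, 0 and 3, 36 and 40, 2 and 4).

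Leaving out 1 library at a time gave 0 to 887, 0 to 505 and 0 to 5 genes for US, S and L against D at day 1, 18 to 3035, 0 to 92 and 12 to 25 at day 7, and 1 to 10, 12 to 33 and 77 higher and 30 lower (1.1e2 in all) to 357 at day 28. Between sizes the ranges were 0 to 9 and 1 to 30 for L against US and S against US at day 1, 1 to 862, 13 to 26 and 11 to 75 for L against US, L against S and S against US at day 7, and 29 to 151, 5 to 64 and 0 to 3 at day 28. L against S at day 1 gave 0 throughout (1759 at an unadjusted p under 0.05 in edgeR with all libraries, and 0 by DESeq2). The larger part turned in at least 1 such fit of US and L at day 1, US at days 7 and 28, S against US at days 1 and 7, L against US at day 7, and the L effect and D at day 28 against day 1. The effects of US, S and L at day 28 against day 1 gave 0 to 92, 3 to 318 and 7 to 318, and D at days 7 and 28 against day 1 gave 0 to 1691 and 3 to 7. Over such fits 861 calls of named genes held and 651 were lost, and 746 list calls held and 198 were lost.

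The other 10 list calls changed their direction in camera's test, 7 of them with the sign of their median. Without US day 28 replicate 3 these were the monocyte and interferon lists in US against D at day 28 (-0.01 and -0.09, up to 0.37 and 0.73 without another library), the interferon list in L against US (0.25, from -0.60) and in S against US (0.21, from -0.63), and the T and NK cell list in S against US (0.12, from -0.51). Without US day 1 replicate 1 it was the T and NK cell list in L against US at day 1 (-0.02, up to 0.68), while the medians kept their sign for the proliferation list in L against US (0.04, from 0.36 with all libraries, up to 0.69) and the NRF2 list in L against US and S against US (-0.01 and -0.02, from -0.21 each with all libraries, down to -0.32 and -0.36). Without S day 1 replicate 1 it was the acute-phase list in S against US (0.21, from -1.04).

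The correlations of effects, for L and US, L and S, and S and US, were 0.64 to 0.73, 0.62 to 0.65 and 0.67 to 0.72 at day 1 with 1 D library left out. They were 0.57 to 0.73, 0.65 to 0.71 and 0.65 to 0.77 at day 7, and 0.55 to 0.57, 0.68 to 0.69 and 0.62 to 0.63 at day 28. Leaving out a D library leaves 2 shared controls.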

Other observations

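The lists and their tests were fixed beforehand, while which of them and of their members are described here was chosen only after the values were seen. At day 1, genes that answer oxidative stress were higher in US lungs as a list of 18 NRF2-linked and metallothionein genes, most of all in replicate 1 (median log2 0.40, camera adjusted p = 3.37e-06, adjusted p = 0.466 with an estimated correlation). Of these 0 were called over all genes and 10 were higher adjusted over the list alone, among them the metallothionein Mt2 (log2 3.54 ± 0.76, edgeR adjusted p = 0.0544), the cystine transporter gene Slc7a11 (2.13 ± 0.51, 0.0581) and Sod2 (0.62 ± 0.15, 0.0581). The score of this list was 1.08 in US replicate 1, against 0.06 and -0.01 in replicates 2 and 3 (-0.17, -0.35 and -0.10 in D). Monocyte-attracting chemokines were higher as a list of 8 (median 0.71, adjusted p = 0.000292, adjusted p = 0.322 with an estimated correlation), with 0 called and 6 higher adjusted over the list alone. Ccl2, the main attractant of monocytes, stood at log2 3.35 ± 0.76 (edgeR adjusted p = 0.0581) and the macrophage growth factor Csf1 at 0.79 ± 0.17 (0.0544). In L lungs of day 1, 0 of 16 immediate early genes were called and 6 were higher adjusted over the list alone, Fos (1.42 ± 0.30, adjusted p = 0.0856) and Egr1 (1.57 ± 0.35, 0.113) among them (median 0.53, adjusted p = 4.28e-06, adjusted p = 0.473 with an estimated correlation). Replicate 1 had a score of -0.33 there, against 0.46 and 0.40. Interferon-stimulated genes were lower as a list of 20 in S lungs of day 1 (median -0.62, adjusted p = 0.000728, adjusted p = 0.834 with an estimated correlation), with 0 called and a score of -0.19 in replicate 1 against -0.57 and -0.70. Genes induced by glucocorticoids were lower as a list of 12 in L than US at day 1 (-0.66, adjusted p = 7.05e-07, adjusted p = 0.674 with an estimated correlation), with 0 called and 10 lower adjusted over the list alone, and lost that call without US replicate 1 (-0.17, adjusted p = 0.982).

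At later days, proliferation genes were lower in S than US lungs at day 28 as a list of 20 (median -0.77, adjusted p = 3.34e-15, adjusted p = 0.674 with an estimated correlation), with 0 members called, either over all genes or over the list alone. Against D they were higher in US (0.42, adjusted p = 4.33e-06, adjusted p = 0.736 with an estimated correlation), a call lost without US replicate 3 (0.19, adjusted p = 0.0773). Smooth muscle markers were lower in L than D lungs at day 28 as a list of 9 (-0.27, adjusted p = 0.000736, adjusted p = 0.465 with an estimated correlation), where Synpo2, an actin-binding protein of muscle, fell 1.33-fold (log2 -0.41 ± 0.09, edgeR adjusted p = 0.00881, its call lost in 2 of 6 fits without 1 library, adjusted p up to 0.0788 without L replicate 1), 8 were not called and 4 were lower adjusted over the list alone. Alveolar macrophage markers were higher in S than D lungs at day 28 (0.30, adjusted p = 0.000235, adjusted p = 0.485 with an estimated correlation), with 0 of 14 called. Cardiomyocyte markers were lower than in D as a list of 10 in US, S and L lungs at day 1 (-1.18, -1.68 and -0.85, adjusted p = 0.00279, 0.000373 and 0.000416), in S lungs at day 7 (-0.95, adjusted p = 0.000191), and in US, S and L lungs at day 28 (-0.66, -0.97 and -0.95, adjusted p = 0.00145, 0.000728 and 0.0249). These had an adjusted p of 0.728 to 0.842 with an estimated correlation and 0 called members. At day 1 the calls for US and L were lost without D replicate 3 (-0.44 and -0.30, adjusted p = 0.189 and 0.224), and that for US also without US replicate 3 (adjusted p = 0.179). At day 28 the calls for US, S and L were lost without D replicate 1 (-0.25, -0.49 and -0.45, adjusted p = 0.21, 0.0742 and 0.285), and those for US and L also without US replicate 2 (adjusted p = 0.295) and L replicate 1 (adjusted p = 0.255). In D lungs, red blood cell markers were higher at day 28 than at day 1 (0.75, adjusted p = 1.8e-09, adjusted p = 0.202 with an estimated correlation), where Slc4a1 rose, 6 of 7 were not called and 4 were higher adjusted over the list alone.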
